A study of Mus musculus with 6 samples.

How the data were processed

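The samples were mouse endothelial cells grown in a complete endothelial medium and exposed for 72 h to lentivirus carrying an empty vector (control, 3 libraries) or RBPMS (3 libraries). Per the labels' protocols, RNA was extracted with Trizol, libraries were made from total RNA with a ribosomal RNA removal kit followed by an NEB RNA library kit, and Illumina sequencing was used. The deposited table holds whole-number counts per gene for the 6 libraries, with gene identifiers, names, coordinates and lengths. Per the submitters' processing notes the authors used FastQC, Salmon and the mm10 build. Versions, the step that turned reads into gene counts and the use of strand are not given in the sources used here. Salmon estimates counts that need not be whole, so how these whole numbers were made is open, and reads of overlapping genes, antisense genes and near-identical copies may be split or assigned wrongly. The table listed 54532 genes, of which 54495 identifiers are in GENCODE M21 (GRCm38) and 53585 have identical coordinates there. Of these genes, 28258 had no count in any library. Groups and replicate numbers came from the sample titles and treatment labels, and the columns were matched to samples by name.

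Counts were analysed as deposited in R 4.3.3. The planned test was edgeR 4.0.16 quasi-likelihood (filterByExpr by group, TMM normalisation, group as the only term, Benjamini-Hochberg adjusted p under 0.05) over all 6 libraries. Levels are TMM-scaled CPM, except that the sums and differences of markers of cell types, the level of Tnni3 and the ratio of Rbpms levels in the closing section are from CPM of the total count, without TMM scaling. Standard errors were derived from the fold change and its F statistic. Comparisons of single values used exact two-sided permutation tests, which cannot go below 0.1 for 3 against 3. Gene lists were tested with camera and fry (limma 3.58.1) on voom log2 CPM, with a preset inter-gene correlation of 0.01 and with an estimated one, for lists with at least 5 measured members. With an estimated correlation camera also uses only the few residual degrees of freedom of the fit. A call lost there need not come from genes that vary together. The 36 lists, the design and the further settings listed next were written before the data were examined. Of these lists, 31 could be tested with all 6 libraries and 33 without control replicate 3, and p-values were adjusted over the tested lists. List medians are of limma-voom log2 fold changes.

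Settings fixed in advance were the replicate number as a block, DESeq2 size factors, total library size, no filter on low counts, at least 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom, a test against a 1.5-fold change, removal of Rbpms, mitochondrially encoded genes and the 20 most abundant genes, and leaving out each library in turn. Library quality weights, per-library trends on gene length and GC content as offsets (loess span 0.3), and all further settings without control replicate 3 were added after the data were seen. Pairs of libraries of a group were compared by a chi-square statistic per degree of freedom over genes with a summed count of at least 10. It was 3.19 to 4.32 for pairs without control replicate 3, so no library was a copy of another of its group.

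The named genes were fixed by a rule before the data were examined: Rbpms and Rbpms2, then among called genes with a mean log2 CPM of at least 1 and groups that do not overlap the 10 highest and 10 lowest log2 fold changes and the 5 smallest p in each direction, then up to 4 called members of each list, or up to 2 abundant members where none was called. Genes without a descriptive symbol were not named, and not every gene the rule allows was named. With all 6 libraries no gene was called, so the rule was applied to the fit without control replicate 3, a choice made after the data were seen. Msln, Mcam and Tnni3 are named as the most abundant markers of their lists.

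The test was tried on simulated counts drawn from the real means and library sizes with known folds. With all 6 libraries it recovered 0%, 2%, 42% and 84% of genes changed 1.25, 1.5, 2 and 4-fold, with 6 false among 70 calls over 13898 simulated genes. With the 5 libraries it recovered 38%, 70%, 90% and 96%, with 18 false among 165 calls over 14123 simulated genes. Each simulated gene had the same spread in every library. In the real data the common biological coefficient of variation was 0.196 with all 6 libraries and 0.049 without control replicate 3. The simulated shares for all 6 libraries therefore need not hold for a design in which 1 library stands apart. The list test called 0 lists when none was changed and 1, the changed one, when p53 targets were raised. These counts were drawn for each gene on its own, so genes of a list did not vary together. In the real data without control replicate 3, estimated inter-gene correlations ran from -0.15 (leukocyte markers) to 0.69 (interferon response). The simulation therefore cannot tell whether list calls with the preset correlation hold where genes vary together. Total counts per library ranged from 15779567 to 23076124, and Rbpms had 908 or more counts in each library.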

Results

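RNA was sequenced from cultured mouse endothelial cells, the cells that line blood vessels, 72 h after lentiviral delivery of an empty vector (control, n = 3) or of RBPMS (n = 3). RBPMS is an RNA-binding protein of the RRM family that takes part in pre-mRNA splicing. The series sets the comparison in the context of heart failure during aging, and the question addressed is which transcripts differ after RBPMS overexpression. Total counts were 15779567, 16229564 and 23076124 in control replicates 1 to 3 and 20453643, 21492957 and 18199702 in RBPMS replicates 1 to 3, and 19799 to 21087 genes had at least 1 count. Nothing in the labels says that the replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

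One control library stood apart from the other 5. Across genes, log2 CPM of control replicate 3 correlated with the other libraries at 0.954 to 0.960, against 0.991 to 0.995 among those 5. Relative to control replicates 1 and 2 it held more of short transcripts, with a median log2 difference of 0.60 in the 20% of genes with the shortest annotated length, and less of long ones, with -0.53 in the longest 20%. Cytosolic ribosomal protein mRNAs took 4.69% of its counts, against 2.29% and 2.37% in the other controls and 2.22% ± 0.02 (SD, n = 3) with RBPMS. Its von Willebrand factor (Vwf) level was 3689 CPM, against a mean of 7776 CPM in the other controls. The comparison is therefore given both with all 6 libraries, as planned, and without control replicate 3. Leaving out each replicate in turn was planned, but the choice to describe genes from the fit without this library was made after the data were seen.

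**Figure D1:**
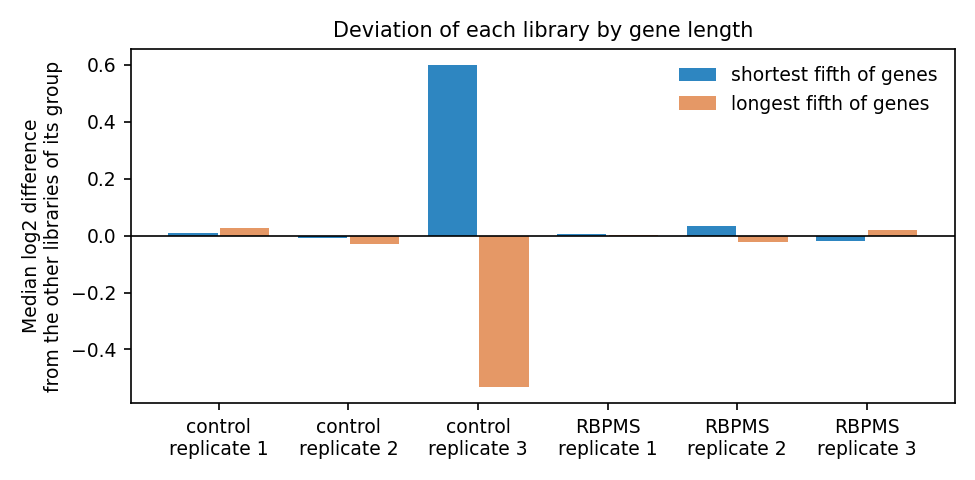
For each library, the vertical axis gives the median log2 difference from the remaining libraries of its group, for the shortest and the longest 20% of genes; control replicates 1 and 2 are each compared with the other of the 2. Control replicate 3 lies at 0.60 and -0.53, while every other bar lies between -0.03 and 0.03.

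The Rbpms gene was 2.41-fold higher in the RBPMS libraries (edgeR without control replicate 3). Rbpms (ENSMUSG00000031586, chromosome 8, 33782643 to 33929863, minus strand, GRCm38) had a normalised level of 56.3 ± 1.04 CPM in controls (SD, n = 3) and 137 ± 9.10 CPM with RBPMS (SD, n = 3), from 908, 921 and 1252 counts in control replicates 1 to 3 and 2673, 3173 and 2429 counts in RBPMS replicates 1 to 3. All 3 RBPMS libraries lay above all 3 controls, which gives the smallest p that 3 against 3 allows (p = 0.1, two-sided exact permutation test of log2 CPM, n = 3 and 3). The log2 fold change was 1.28 ± 0.10 (SE) with all 6 libraries, with an edgeR quasi-likelihood adjusted p of 0.061, and 1.27 ± 0.059 without control replicate 3, with an adjusted p of 3.6e-11. Whether the vector carried the mouse or another coding sequence is not given in the sources used here, so these counts need not hold all transgene transcripts. Its paralog Rbpms2 (ENSMUSG00000032387) rose in the fit without control replicate 3 (log2 fold change 0.59 ± 0.16, adjusted p = 0.030) and had a log2 fold change of 0.36 with an adjusted p of 0.59 over all 6 libraries.

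Across all 6 libraries no gene passed the planned edgeR quasi-likelihood test among 13898 tested, with 1050 genes at an unadjusted p under 0.05, while DESeq2 called 56 genes (41 higher, 15 lower) and limma-voom 0. Without control replicate 3 the same edgeR test called 1022 of 14123 genes, 538 higher and 484 lower with RBPMS. With 1 RBPMS replicate left out as well it called 616 (without RBPMS replicate 1) to 1017 (without RBPMS replicate 3). In a test against a 1.5-fold change 8 genes passed, and failing that test with 2 and 3 libraries does not show that a change was small. In 2 libraries against 3, simulated counts with known changes gave 18 false calls among 165 at the adjusted p threshold of 0.05, so the false share there was above the nominal level. All folds and adjusted p-values from here on come from the edgeR fit without control replicate 3 (2 controls, 3 RBPMS libraries) unless stated otherwise, and no named gene passed the planned edgeR test over all 6 libraries.

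The genes with the highest fold were at low levels in controls. Olfm4, which encodes a secreted olfactomedin glycoprotein, rose from a mean of 4.25 CPM in control replicates 1 and 2 to 20.5 CPM (log2 fold change 2.27 ± 0.19, adjusted p = 2.4e-07). Daam2, a formin of Wnt signalling, rose from 6.24 to 25.4 CPM (2.02 ± 0.12, adjusted p = 2.9e-09), and it had 2.95 CPM in control replicate 3. Atp8b3, a phospholipid flippase, rose by a log2 fold change of 1.85. The antiviral 2'-5' oligoadenylate synthetase gene Oas3 (1.82), Ccdc141 (1.81), the phosphatase Ptp4a3 (1.64), the interferon-inducible Ifi207 (1.58), the prostaglandin transporter Slco2a1 (1.38) and the prostaglandin D synthase Hpgds (1.35) also rose. Each of these 6 had a mean of at most 1.18 CPM in control replicates 1 and 2, and all 6 lay higher in the 3 RBPMS libraries than in all 3 controls. Such separation was common: over all 6 libraries the groups did not overlap for 24.7% of 13898 tested genes, against 10% by chance. In the 5 libraries, where the naming rule asked for it, the share was 37.4% of 14123, against 20% by chance. Rps27rt, a ribosomal protein gene copy whose reads can be shared with its parent gene, is uncertain: its log2 fold change was 1.41 without control replicate 3 and -0.35 with it, and that library held 202 CPM against a mean of 25.0 CPM in the other controls. Without RBPMS replicate 2 as well it was 0.72.

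Among rising genes not yet named, those with the smallest p were P2rx7, an ATP-gated ion channel (40.7 to 75.1 CPM, log2 fold change 0.89 ± 0.068, adjusted p = 1.2e-07), the neutral ceramidase Asah2 (0.57 ± 0.047), the tetraspanin Tspan18 (0.51 ± 0.047), the kinase Rps6ka2 (0.64 ± 0.060) and Eda2r (0.62 ± 0.057), a receptor of the tumour necrosis factor receptor family. In all 5 the 3 RBPMS libraries lay above all 3 controls.

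Elastin (Eln) had the lowest fold of all named genes. Its mean fell from 80.7 CPM in control replicates 1 and 2 to 38.2 CPM (log2 fold change -1.08 ± 0.070, adjusted p = 7.4e-09), and control replicate 3 lay at 67.6 CPM. The metalloreductase gene Steap1 (-1.08), the adhesion receptor Adgrb2 (-1.05), Siglec1 (-0.98), a sialic acid receptor best known from macrophages, the prokineticin receptor Prokr1 (-0.95), the mitochondrial malic enzyme Me3 (-0.90), Hopx (-0.89) and C1ql4 (-0.88) also fell. So did the hyaluronan synthase Has3 (-0.83), whose locus overlaps Chtf8, and Sarnp (-0.90), whose locus overlaps Dnajc14 and Ormdl2, so that these 2 are uncertain where counting could split reads. Among falling genes not yet named, the smallest p belonged to Masp1, a protease of the lectin pathway of complement that overlaps Rtp4 (-0.62 ± 0.050, adjusted p = 2.1e-07), fibronectin (Fn1, -0.56 ± 0.050), Nptx1 (-0.78 ± 0.073), matrilin 2 (Matn2, -0.48 ± 0.049) and Tmem119 (-0.63 ± 0.065). Over all 6 libraries the groups overlapped for Fn1, Siglec1, Prokr1, Has3, Nptx1 and Masp1, all lower in control replicate 3 than in the other controls (Fn1 at 124 against 449 CPM), and their log2 fold changes were -0.17, -0.51, -0.63, -0.49, -0.49 and -0.45. The fold of Sarnp was -1.39 over all 6 libraries, and without control replicate 3 it was -0.23 when control replicate 2 was left out as well and -1.35 when control replicate 1 was. Steap1 lost its call without control replicate 1 as well (-0.45, adjusted p = 0.53).

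Among 25 measured targets of the tumour suppressor p53, 12 rose and 0 fell (13 and 0 adjusted over the list alone), among them Ccng1 (log2 fold change 0.49 ± 0.050), Trp53inp1 (0.48 ± 0.047), the p53 ubiquitin ligase Mdm2 (0.33 ± 0.052) and Eda2r. The cyclin-dependent kinase inhibitor Cdkn1a rose from 256 to 315 CPM (0.30 ± 0.049, adjusted p = 5.1e-04). The list lay above other genes in camera with a preset correlation (adjusted p = 3.1e-09, and 8.7e-05 over all 6 libraries), and the call is lost with an estimated correlation (adjusted p = 0.323, and 0.723 over all 6 libraries). In fry the adjusted p was 0.071, and 0.035 over all 6 libraries.

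Calls among cell division genes were all downward. Of 38 measured G2/M and mitosis genes 15 fell and 0 rose (33 fell adjusted over the list alone), and all 38 had a negative log2 fold change. Plk1, a mitotic kinase, fell from 33.6 to 23.5 CPM (-0.51 ± 0.087, adjusted p = 8.6e-04), and Ccnb2 (-0.48 ± 0.098), Anln (-0.38 ± 0.070) and Top2a (-0.35 ± 0.063) fell too. Of 39 S phase and DNA replication genes 6 fell and 0 rose (12 fell adjusted over the list alone), including E2f8 (-0.46), Uhrf1 (-0.42), Mcm2 (-0.34) and Rrm2 (-0.32). The median log2 fold change of the S phase list was -0.16, and -0.075 without control replicate 1 as well. Both lists were lower than other genes with a preset correlation (camera adjusted p = 3.2e-19 and 9.4e-07) and neither with an estimated one (adjusted p = 0.338 and 0.533). The same held over all 6 libraries, with medians of -0.28 for G2/M and -0.20 for S phase. There the camera adjusted p was 2.2e-09 and 7.5e-06 with a preset correlation and 0.723 for each with an estimated one, and 0 members were called. Control replicate 3 lay below the other controls for Top2a, Uhrf1 and E2f8 (125, 32.4 and 11.6 CPM against 168, 64.0 and 24.0 CPM), and these genes then did not separate the groups (log2 fold changes of -0.22, -0.16 and -0.18 over all 6 libraries). Anln had -0.25 and Ccnb2 -0.73 over all 6 libraries, and Mcm2 -0.20 without control replicate 1 as well.

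**Figure D2:**
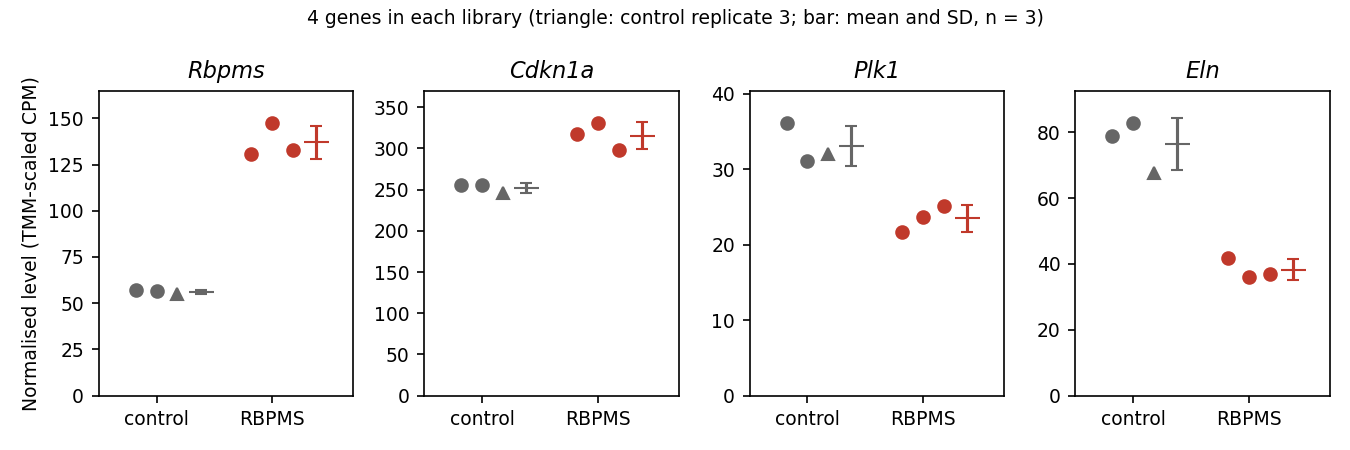
Normalised level (TMM-scaled CPM, vertical axis) of 4 genes in each library, with the mean and SD of each group (n = 3); triangles mark control replicate 3. Rbpms and Cdkn1a lie higher in all 3 RBPMS libraries than in all 3 controls, and Plk1 and Eln lower.

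Interferon response genes were higher as a list. Of 34 measured members 7 rose and 0 fell (15 rose adjusted over the list alone), and 31 had a positive log2 fold change. Besides Oas3 these included Ifit3 (105 to 159 CPM, log2 fold change 0.61 ± 0.12, adjusted p = 2.2e-03), Trim30a (0.32 ± 0.068) and Ddx58, which encodes the RNA sensor RIG-I (0.21 ± 0.050, 0.32 over all 6 libraries). Camera gave an adjusted p of 1.1e-08 with a preset correlation and an adjusted p = 0.535 with an estimated correlation. The median log2 fold change of the list was 0.22, and with 1 more library left out it was 0.11 without control replicate 1, 0.35 without control replicate 2, 0.14 without RBPMS replicate 1 and 0.34 without RBPMS replicate 3. Over all 6 libraries the median was 0.30 (camera adjusted p = 6.0e-05 with a preset and 0.723 with an estimated correlation). There the preset call was lost without control replicate 1 (median 0.12, camera adjusted p = 0.0593), and the median was 0.13 without RBPMS replicate 1. Both groups received lentivirus, so the contrast is not one of infected with uninfected cells. Whether the groups were infected to the same extent was not tested.

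Endothelial identity genes did not move in one direction as a list: of 28 measured members 3 rose and 4 fell (7 and 5 adjusted over the list alone, camera adjusted p = 0.801). Vwf fell from 7776 to 5671 CPM (log2 fold change -0.45 ± 0.053, adjusted p = 1.7e-05), and with control replicate 3 at 3689 CPM its log2 fold change over all 6 libraries was -0.18 (adjusted p = 0.765), while the vascular matrix protein gene Mmrn2 (0.44 ± 0.060) and the transcription factor gene Erg (0.21 ± 0.045) rose. The vascular endothelial growth factor receptor genes went different ways, with Flt1 (-0.22 ± 0.045) and Kdr (-0.21 ± 0.049) falling and Flt4 rising (0.31 ± 0.049). Over all 6 libraries the log2 fold change was 0.02 for Flt1, -0.01 for Kdr, 0.62 for Flt4 and 0.32 for Erg. Of 21 angiogenesis and tip cell genes 3 rose and 6 fell. In the arterial and Notch list, 4 of 16 rose and 2 fell, with the Notch ligand Jag1 (0.48 ± 0.048) and the connexin gene Gja4 (0.91 ± 0.14) higher and the connexin gene Gja5 (-0.38 ± 0.099, -0.20 without control replicate 2 as well) lower. Neither list was shifted in one direction against other genes (camera adjusted p = 0.467 and 0.109). In fry's test for change in either direction both passed (adjusted p = 0.0020 and 0.0012), as did 29 of all 33 lists tested. Over all 6 libraries 0 lists passed that test.

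Extracellular matrix genes were lower on balance, with 3 of 30 measured members higher and 10 lower (5 and 12 adjusted over the list alone). Beside Eln and Fn1, the collagen gene Col8a1 fell (-0.42 ± 0.053), and the metalloproteinase inhibitor Timp3 rose (0.42 ± 0.046, adjusted p = 6.5e-06, and 0.79 over all 6 libraries). Camera gave an adjusted p = 0.00238 with a preset correlation and an adjusted p = 0.338 with an estimated correlation. Over members of no other list the call was lost, with a median log2 fold change of -0.054 against -0.13 over the whole list (adjusted p = 0.242). Over all 6 libraries the list's median log2 fold change was 0.11, with the opposite sign of its camera direction, and the camera adjusted p was 0.992. Control replicate 3 differed from the other controls by a median of -0.66 on the log2 scale over the 29 members tested in all 6 libraries. The fibroblast marker list was lower in the same fit, with a median log2 fold change of -0.38 over 5 measured members, of which 2 fell (camera adjusted p = 0.0130, and 0.338 with an estimated correlation).

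Several metabolic and RNA-processing lists were lower. Of 19 glycolysis genes 5 fell and 0 rose (8 and 1 adjusted over the list alone), among them the glucose transporter Slc2a1 (-0.26 ± 0.047) and the phosphofructokinase Pfkl (-0.24 ± 0.048). In the list of amino acid and endoplasmic reticulum stress, 7 of 39 fell and 1 rose (15 and 2 adjusted over the list alone). The amino acid transporter Slc7a5 (-0.39 ± 0.067), Ddit4 (-0.27 ± 0.050) and the disulfide isomerase Pdia6 (-0.24 ± 0.047) fell, and the stress-inducible Sesn2 rose (0.39 ± 0.070). Of 46 splicing regulators 10 fell and 2 rose (11 and 2 adjusted over the list alone). The 2 that rose were Rbpms itself and Rbpms2, and Tra2b (-0.29 ± 0.051), Srsf9 (-0.29 ± 0.051) and Hnrnpd (-0.30 ± 0.055) were among those that fell. The camera adjusted p was 1.9e-04 for glycolysis, 3.4e-04 for the stress list and 0.00278 for splicing, and with an estimated correlation the adjusted p was 0.323, 0.323 and 0.633. Over all 6 libraries glycolysis (median -0.23) and the stress list (-0.18) had a camera adjusted p of 0.037 and 0.0010, and 0.723 for each with an estimated correlation. Glycolysis lost that 6-library call without control replicate 1 (0.081) or 2 (0.095) or RBPMS replicate 2 (0.058) or 3 (0.096). Splicing was not called without control replicate 1 as well (camera adjusted p = 0.141) or over all 6 libraries (0.138), and over all 6 the log2 fold changes of Slc7a5, Pdia6 and Srsf9 were -0.22, -0.52 and -0.52.

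Transcripts from the mitochondrial genome were higher, and nuclear genes of oxidative phosphorylation slightly lower. Of 12 mitochondrially encoded mRNAs 5 rose and 0 fell (10 rose adjusted over the list alone), including mt-Nd4 (log2 fold change 0.27 ± 0.054) and mt-Co3 (0.40 ± 0.097, 0.11 over all 6 libraries), whose annotated loci overlap mt-Nd4l and mt-Atp6. Without control replicate 1 as well mt-Nd4 was 0.18, and without control replicate 2 as well mt-Co3 was 0.23. As a share of all counts these mRNAs took 2.72% ± 0.05 in controls and 3.11% ± 0.15 with RBPMS (SD, n = 3 and 3, two-sided exact permutation p = 0.1, 0.133 after Benjamini-Hochberg adjustment over 8 measures), higher in all 3 RBPMS libraries than in all 3 controls. Of 45 nuclear-encoded subunits 1 fell, Cox5b (-0.35 ± 0.072, -0.70 over all 6 libraries), and 0 rose, with 43 at a negative log2 fold change. Cytosolic ribosomal protein genes had 5 of 49 lower and 0 higher (10 lower adjusted over the list alone), such as Rplp2 (-0.29 ± 0.048, -0.77 over all 6 libraries). The median log2 fold change was -0.10 for the nuclear-encoded and -0.09 for the ribosomal list, against -0.43 and -0.44 over all 6 libraries, where control replicate 3 exceeded the other controls by a median of 0.94 and 1.07 on the log2 scale. The ribosomal median was -0.048 without control replicate 2 as well and -0.058 with length and GC trends removed. Camera gave adjusted p-values of 6.2e-08 for the mitochondrial, 5.1e-06 for the nuclear-encoded and 9.4e-07 for the ribosomal list, and with an estimated correlation the adjusted p was 0.338, 0.323 and 0.435. Over all 6 libraries the mitochondrial list was not called (camera adjusted p = 0.167).

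**Figure D3:**
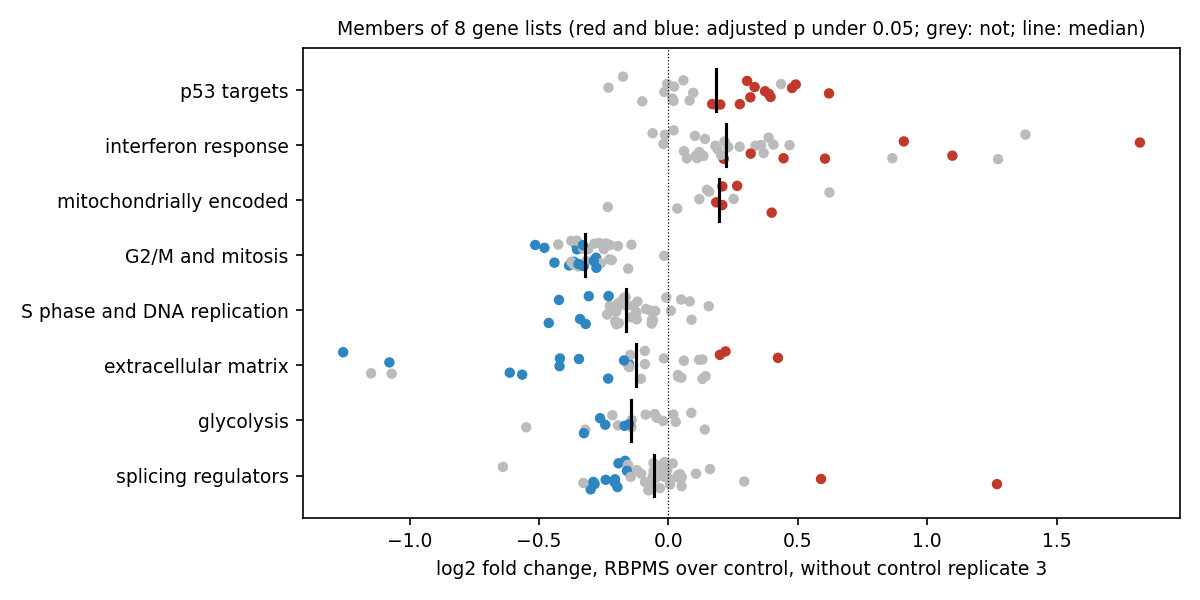
Each point is a measured member of 1 of 8 gene lists, placed by its edgeR log2 fold change (RBPMS over control, without control replicate 3, horizontal axis); coloured points passed an adjusted p of 0.05 and the black line is the list's median. In the p53 list 12 of 25 members rose, and in the G2/M list 15 of 38 fell.

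The senescence list fell on balance and the apoptosis list rose, both narrowly without control replicate 3. In the senescence and secretory phenotype list 6 of 26 fell and 1 rose (10 and 3 adjusted over the list alone): the nuclear lamin gene Lmnb1 (-0.42 ± 0.084) and the cell cycle inhibitors Cdkn2c (-0.32 ± 0.069) and Cdkn1b (-0.25 ± 0.050) fell, and the member that rose was Cdkn1a. The fall of the list does not show less senescence, since its members, Lmnb1 among them, need not all rise in senescent cells. Among 24 apoptosis regulators 3 rose and 1 fell (4 and 1 adjusted over the list alone), with the survival factor Bcl2l1 (0.23 ± 0.050) and the death-promoting Bbc3 (0.37 ± 0.087) higher and the death-promoting Bmf (-0.37 ± 0.080) lower. Camera gave an adjusted p of 0.0479 for each with a preset correlation and an adjusted p = 0.338 for each with an estimated correlation. With 1 more library left out, the senescence list lost its call without control replicate 1 (camera adjusted p = 0.259), RBPMS replicate 1 (0.0690) or RBPMS replicate 3 (0.0693), and the apoptosis list without control replicate 1 (0.155), RBPMS replicate 1 (0.0690) or RBPMS replicate 2 (0.0615). The senescence list also lost it with length and GC trends removed (0.0921), and the apoptosis list over members of no other list (0.242). Over all 6 libraries the senescence list was called with a preset correlation (median log2 fold change -0.24, camera adjusted p = 0.0077). It was not with an estimated one (0.723), and control replicate 3 exceeded the other controls there by a median of 0.20 on the log2 scale. The apoptosis list was not called over all 6 libraries (camera adjusted p = 0.519), and the log2 fold changes of Bcl2l1, Bmf and Cdkn2c were 0.13, -0.21 and -0.52.

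The remaining lists were not shifted in one direction against other genes by camera. TGF-beta and BMP targets had 1 of 19 lower (Smad7, -0.50 ± 0.10), inflammatory adhesion and NF-kB 2 of 23 lower (Cxcl1, -0.32 ± 0.077 and -0.19 without control replicate 1 as well, among them), and shear response and nitric oxide 1 of 17 higher and 3 lower. Venous and lymphatic genes had 1 of 8 higher and 2 lower, cell junctions and barrier 1 of 17 lower, endothelial to mesenchymal transition 1 of 16 higher and 2 lower, and smooth muscle contractile genes 1 of 14 higher and 2 lower. Antigen presentation had 2 of 12 higher and 1 lower, immediate early and AP-1 genes 2 of 27 higher, YAP/TAZ targets 2 of 18 lower, and the hypoxia response 2 of 19 higher and 4 lower. Cholesterol synthesis had 0 of 23 called, fatty acid uptake and oxidation 1 of 20 higher, and antioxidant and NRF2 targets 2 of 24 higher and 2 lower. The replication-dependent histone list, with 7 measured members, had Hist1h1c higher (0.31 ± 0.077, -0.02 over all 6 libraries) and H1f0 lower (-0.33 ± 0.047), and H1f0 is a replication-independent linker histone placed in that list in error.

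Markers of other cell types were low. In CPM of the total count, without TMM scaling, fibroblast markers summed to 33.9 to 53.9 CPM per library, mostly from Pi16, leukocyte markers to 50.6 to 67.1 CPM, mostly from Cd68, epithelial and mesothelial markers to 20.1 to 29.5 CPM, mostly from Msln, and cardiomyocyte markers to 1.96 to 4.42 CPM, with Tnni3 the most abundant. Pericyte and smooth muscle markers summed to 370 to 469 CPM, nearly all from Mcam, which endothelial cells also express. Endothelial identity genes summed to 22544 to 28892 CPM. Of 5 measured fibroblast markers 2 fell (camera adjusted p = 0.0130, 0.338 with an estimated correlation and 0.0503 without RBPMS replicate 3 as well), with Pi16 at -0.38 ± 0.10 (-0.21 without control replicate 2 as well), and of 5 leukocyte markers 1 rose, Cd68 (0.34 ± 0.072, list adjusted p = 0.919). The pericyte, epithelial and cardiomyocyte lists had 3 measured members each, too few to test.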

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

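Settings without control replicate 3 beyond the planned leaving-out, the quality weights and the length and GC offsets were chosen after the data were seen. With all 6 libraries, edgeR called 0 genes in the planned test, 5 with no filter on low counts and 3 with length and GC offsets, DESeq2 called 56, and limma-voom with library quality weights 1087. Leaving out 1 library gave 0 to 1022 calls, 1022 without control replicate 3 and 0 without any other. Of those 1022 calls, 895 were kept with quality weights, a fit that nearly leaves out control replicate 3 (weight 0.029, the lowest, against 3.31 for the highest), 945 with limma-voom and 747 with DESeq2 in the 5 libraries, where 3560 genes had no adjusted p. In the 5 libraries 8 genes passed the test against a 1.5-fold change, which asks for a larger effect, 1385 were called with length and GC offsets, and leaving out 1 more library gave 415 (without control replicate 1) to 1017, where a lone control is assumed to vary like the other libraries. Of the 84 genes named from this fit none changed sign in these settings, and 34 lost their call without control replicate 1 as well, 14 without control replicate 2, 6 to 8 without an RBPMS replicate, 2 with limma-voom, 78 against a 1.5-fold change and 0 with either other scaling or the offsets. DESeq2 gave an adjusted p for 73 of them, of which 5 lost their call. The log2 fold change of Rbpms was 1.23 to 1.32 with each library left out, and passed the threshold without control replicate 3 (1.27), with no filter (1.28, adjusted p = 0.0027), DESeq2 (1.28), quality weights (1.26) and offsets (1.18, adjusted p = 0.035). Adjusted p-values ran from 3.45e-25 with DESeq2 to 0.844 without RBPMS replicate 1.

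Camera called 9 of 31 lists with all 6 libraries and 14 of 33 without control replicate 3. An estimated correlation gave 0 in both. In the 5 libraries that estimate was -0.0044 for the stress list and -0.020 for glycolysis, below the preset 0.01. Their unadjusted camera p still rose, from 9.4e-05 to 0.019 and from 4.5e-05 to 0.021. Fry called 2 lists over all 6 libraries (p53 targets and glycolysis) and 1 without control replicate 3 (the stress list). It called 0 with the replicate block or with any 1 library but control replicate 3 left out of the 6. For change in either direction fry gave 0 over all 6 libraries and 29 without control replicate 3. Leaving out 1 library gave 8 to 14 lists, and 1 more besides control replicate 3 gave 11 to 16.

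Signs of some log2 fold changes over all 6 libraries turned. With the replicate block Rps27rt was 0.290, Fn1 0.0354, Kdr 0.0192 and Hist1h1c 0.0366, and with limma-voom 0.206, 0.0263, 0.0123 and 0.0305. With quality weights Rps27rt was 1.31, Flt1 -0.216 and Hist1h1c 0.292, and with offsets 0.284, -0.198 and 0.205. With each library left out, Rps27rt ran from -1.04 to 1.41 and Hist1h1c from -0.193 to 0.314, both highest without control replicate 3, as was mt-Co3 (-0.0840 to 0.399). Lowest without that library were Siglec1 (-0.983 to 0.0171), Fn1 (-0.565 to 0.147), Flt1 (-0.224 to 0.160), Kdr (-0.207 to 0.109), Uhrf1 (-0.423 to 0.0350), E2f8 (-0.462 to 0.0291) and the median of the extracellular matrix list (-0.125 to 0.281). That median, 0.115 in the planned test, stayed above 0 in the settings where the list test itself turned from lower to higher. It was 0.126 with the block, 0.123 at 1 CPM in 3 libraries, 0.203 over members of no other list and the same 0.115 with fry. Without control replicate 1 it was 0.204, and without control replicate 2 it was 0.281. Of these values only those without control replicate 3, and those with quality weights, passed the threshold, and beyond the removal or weighting of that library the cause was not tested.

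The replicate numbers showed no pairing of the samples, in a check that could hardly show it. Correlations of deviations from the group means were 0.05, -0.03 and 0.01 for numbers 1 to 3. Of 6 libraries 1 correlated best with its own number. The control mean included control replicate 3, whose distance from the other controls sets most of every control deviation, so pairing is not excluded. With the replicate block 0 genes (702 at an unadjusted p under 0.05) and 8 lists were called, and the log2 fold change of Rbpms was 1.28. Simulated 1.5-fold changes were recovered in 2% of genes with all 6 libraries, in a fit without the replicate block. The simulated spread was the same in every library, so this share does not give the power of the block fit.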

Other observations

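The tests of the length trend and of swapped labels for control replicate 3, the restriction of the motif search to protein-coding genes and the partial correlations were chosen after the result was seen.

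Control replicate 3 stood apart in its length trend and composition, and apart from cells of another type no biological explanation for it was tested. After a per-library trend on gene length was removed, its median correlation with the other 5 libraries was 0.967, still under the lowest value of 0.991 among those 5. This argues against a trend on annotated length as the whole cause. The trend used 1 annotated length per gene, so an effect of the length of the transcripts present in these cells may remain. After thinning all libraries to 15779567 counts the median correlation was 0.953, which argues against depth. Its Rbpms level, in CPM without TMM scaling, was 0.415 of the lowest RBPMS library, against a swap with one of those. The highest median difference in a list of another cell type was 0.43 on the log2 scale (cardiomyocyte markers, Tnni3 at 2.86 CPM). Each of these medians over the 5 cell types rests on 2 or 3 genes, so they argue only against a large share of cells that express those few genes. Replication-dependent histone mRNAs, which lack a poly(A) tail, lay a median of 0.41 higher on the log2 scale (6 measured of 22, -0.23 to 1.22). Hist1h1c was at 58.2 against 32.8 CPM, Hist1h2bc at 10.5 against 4.27 and Hist1h2be at 2.82 against 1.90, but Hist1h1d at 0.57 against 0.78. These values cannot decide on selection of polyadenylated RNA in this library alone. H1f0, which is polyadenylated, gave most of the list's counts in the other controls (298 CPM). Whether the remaining measured transcripts lack a tail here is unknown. A different library preparation or RNA state may also remain after the length trend (0.967) and was not tested.

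The 1022 calls without control replicate 3 could come from technical differences between the groups. Removing length and GC trends kept 98.1% of them, and thinning to one total kept 91.9%, both with their direction. This argues against trends on annotated length and GC, and against depth, as their cause. Of the 10 splits of the 5 libraries into 2 and 3, 1 gave as many calls, the real one, and the highest other gave 3. For all 6 libraries the real split gave 0 and the highest other 0, and since no split can give fewer than 0, the count of 10 of 10 with as many says nothing about chance. Both designs have too few splits for a share under 0.05.

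RBPMS proteins bind RNA with tandem CAC motifs, so a candidate explanation for part of the differences is direct binding in 3' UTRs. Across 10770 of 11859 protein-coding genes tested (90.8%), log2 fold change without control replicate 3 correlated with the density of CAC pairs spaced 1 to 12 nt apart at Spearman 0.115, against 0.050 for ACC and 0.047 for CCA, each with a permutation p of 1e-04, the smallest 10000 permutations can give (1e-04 after adjustment over 3 motifs). Genes are not independent replicates, and other splits of the same 5 libraries gave a CAC correlation of up to 0.161 in size, so differences between single libraries produce values as large and binding cannot be told apart from them. With the other motifs, UTR length and GC held constant by rank, the CAC value was 0.097 in the real split and at most 0.086 in the others. The median CAC density was 3.69 per kb in genes that rose, 2.45 in genes that fell and 2.62 in the rest, against 2.23, 1.83 and 1.74 for ACC and 5.13, 4.27 and 4.03 for CCA.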
